A study of Chlamydomonas reinhardtii with 2 samples.

How the data were processed

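The deposited file of the N-replete library holds 1 record per alignment of 1 read, with the length of the read, its aligned share, the identity, the read and genome positions, the strand and the splice direction, followed by its exons. The authors aligned the reads with GMAP version 2007-09-28, with options that set the maximum intron length and the maximum total intron length to 1000 bases, per the file headers. GSNAP, a companion program, is named in the submitters' processing notes. The version of the genome is not given in the sources used here. Up to 5 places per read are listed, and reads without an alignment have no record. These are raw alignment records in no expression unit, so no read count per gene came with them and counts were made here. Cells, RNA extraction, SMART cDNA synthesis, PCR, SfiI digestion and size fractionation are as the labels' protocols describe. PCR, digestion and size selection can each change the relative abundance of a product, so read numbers are not molecule numbers.

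Groups were taken from the labels, which give 1 N-replete and 1 N-deprived library. The N-deprived library was not analysed here, so no group comparison, fold change or p-value between conditions was computed. The designs fixed before the data were examined provided for counts per gene and for 18 lists of genes. The available gene table belongs to assembly v5.5. Genes of that table ended past the end of the sequence of the same number at 11 of the 16 chromosomes that could be compared, so the builds differ and no gene was assigned. The lists were therefore not evaluated, and the fallback fixed at the same time was used, which names the 10 loci with the most reads. The locus on sequence 17 that is described at the end was chosen after its values were seen.

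The best place of a read was the listed alignment with the highest product of identity and aligned share. A read was left out of locus counts when another place that did not overlap scored within 0.1 percentage points. Because 5 places at most are listed, ties with further places cannot be seen. Loci are runs of overlapping alignments on 1 sequence, on either strand, including their introns, so neighbouring genes that overlap are joined. Gaps of at least 20 bases on the genome were called introns, and the splice signs of the records gave their borders and direction. A locus with at least 50 reads was given a direction when at least 10 directed spliced reads had at least 95% of them in 1 direction, or, for cDNA ends, when at least 10 end reads had at least 90%. End reads were read starts with 34 to 44 leading unaligned bases for the 5' end and 45 to 57 for the 3' end, ranges set on the spliced loci after looking at them. An end position needed at least 10 such reads. Boundary crossings required 10 aligned bases on each side for unspliced reads, and each spliced read counted at both boundaries. Coverage along a transcript was taken over the covered exonic sequence in 10 equal bins.

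Implied chromosome lengths came from the differences between the whole-genome and the per-sequence positions in the records. Shares carry exact Clopper-Pearson 95% intervals, the interval of a median is from order statistics, and that of the mean coverage share is the normal interval over loci. With 223396 tie-free reads, shares of the whole library have narrow intervals, but a locus with 10 reads has a wide interval relative to its count. The reading of records, the removal of tied reads and the calling of introns were tested on simulated alignments with known answers. The code recovered 200 of 200 transcripts with their read count, by simulated position, 189 of 189 introns and 280 of 280 tied reads. The joining of reads into loci was checked only for not merging simulated transcripts. Direction by cDNA ends, end positions, coverage bins and read-through were not part of this test.

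The alternatives chosen before the data were examined were reads with 1 alignment, ties split equally, identity of at least 95% with an aligned share of at least 90%, duplicates counted once, and a minimum gap of 50 bases. 8 further alternatives, namely identity of at least 95% alone, loci joined by aligned bases, leaving out the most abundant locus, leaving out introns read through in most crossings, a minimum of 2 or of 10 reads per intron, and leaving out the largest locus of each sequence or both low-identity loci of sequence 14, were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.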

Results

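The series examined the transcriptome of the unicellular green alga Chlamydomonas reinhardtii under nitrogen supply and nitrogen deprivation by pyrosequencing of cDNA. Cells of strain dw15.1, which carries the cell wall mutation cw15 and the mutation nit2 in the regulator of nitrate assimilation, were grown in acetate-containing TAP medium under continuous light. A culture at 5000000 cells per mL was divided, and the cells were kept for 48 hours in 50 mL of medium with 10 mM ammonium (N-replete) or without nitrogen (N-deprived). Each condition had 1 biological replicate. The cDNA was primed at the poly(A) tail, extended to the 5' end with the SMART method, amplified by PCR and size-selected. The values below come from the N-replete library. The N-deprived library was not analysed here, so the comparison of the conditions, which the design was made for, was not carried out. With 1 library there is no replicate error. The intervals are exact Clopper-Pearson 95% binomial intervals and cover counting error only, since PCR copies are not independent molecules.

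The N-replete library held 239585 reads with at least 1 alignment to the genome and 50972904 bases in these reads. The median read length was 232 bases, with quartiles of 181 and 258. The median identity of the best alignment was 99.2%, and the median aligned share of a read was 77.6%. Among tie-free reads outside the most abundant locus, described below, the median aligned share was 95.9% (quartiles 79.9 and 100). Of the aligned reads, 203010 had exactly 1 place on the genome (84.7%, interval 84.6 to 84.9). A further 22790 had 2 to 5 places and 13785 had more than 5. A total of 16189 reads (6.76%, interval 6.66 to 6.86) scored equally at a second place and entered no locus count, which left 223396 reads. Reads without an alignment have no record, so the share of the library that aligned is unknown. The genome build is not given in the sources used here. The sequences carry the numbers 1 to 17, plus a sequence named NA whose makeup is not given in the sources used here, and all positions below are in that build. Genes, exons and untranslated regions at these positions were not assigned, because no annotation of that build was used here.

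A single short product took the largest share of the tie-free reads in the N-replete library, but not when duplicates were counted once or when both identity and aligned share were limited. The locus on sequence NA between bases 199827 and 200235 held 87954 reads, 39.4% (interval 39.2 to 39.6) of the tie-free reads. No other locus reached 2% of them. Tie-free reads formed 14103 loci, of which 1034 had at least 10 reads, 345 had at least 50 and 18 had at least 1000. No minimum aligned length was set, so the counts include very narrow loci. Examples on sequence 2 lie at 3126281 to 3126301 (296 reads) and at 8122487 to 8122512 (176 reads). Whether such loci are transcripts was not tested. The 1034 loci with at least 10 reads held 88.9% of the tie-free reads.

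The reads of the most abundant locus covered a sharply bounded product of 167 bases, from base 200018 to base 200184. Exactly these bases were aligned in 56974 of its reads (64.8%, interval 64.5 to 65.1). Reads ran in both directions, 51758 along the plus strand and 36196 along the minus strand. Of the plus reads, 92.8% began at base 200018, most often after 39 unaligned bases. Of the minus reads, 85.9% began at base 200184, most often after 63 unaligned bases. None of its reads had a splice direction, and 3.42% of these tie-free reads had another place on the genome. With the 3653 tied reads of the locus included, the share was 7.27%. Counting reads with the same start, end and strand once reduced the locus to 1665 alignments, or 1.41% of all counted this way, the fifth largest share, behind 2.78% at the locus on sequence 6 at 7308780. Requiring an identity of at least 95% together with an aligned share of at least 90% left it at 0.572% of the reads that met both, outside the 10 loci with the most reads, and identity of at least 95% alone left it at 40.6%.

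**Figure D1:**
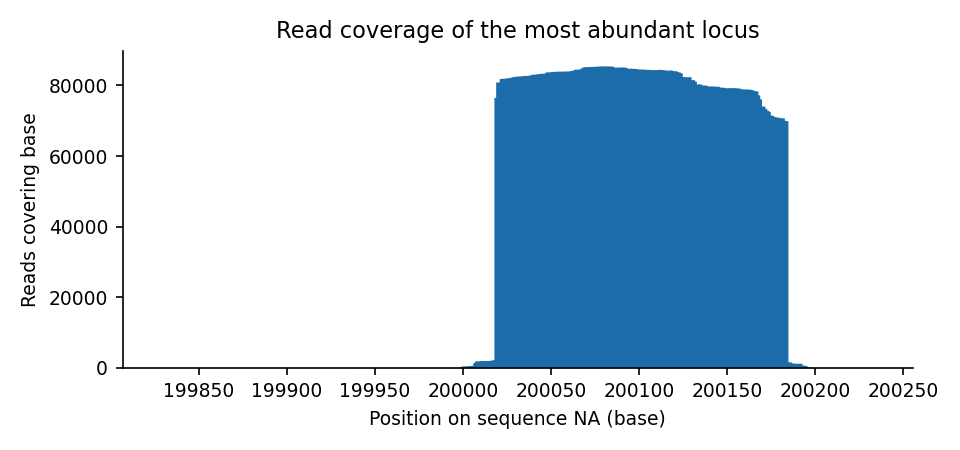
Read coverage of the most abundant locus of the N-replete library. The x axis gives the position on sequence NA in bases and the y axis the number of tie-free reads that cover each base. Coverage rises at base 200018 and falls after base 200184, the ends of the 167-base product.

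The next 9 loci together held 21920 reads, 16.2% (interval 15.99 to 16.4) of the 135442 reads outside the most abundant locus. On sequence 6, the locus at 7308780 to 7310439 followed with 3993 reads (1.79%, interval 1.73 to 1.84). It was unspliced apart from 3 reads, its transcript ran on the plus strand by its cDNA ends, and the distance between the commonest ends was 1264 bases. Of its reads, 98.9% had another place on the genome, and 3859 of the 3993 were also listed at the locus on sequence NA at 6688977 to 6690584. That second locus held 2037 reads and was likewise unspliced apart from 7 reads. A further 931 reads scored equally at both places, so the division of reads between this pair of similar loci is uncertain. Among reads with exactly 1 alignment, the shares of the pair fell to 0.0217% on sequence 6 and 0.0182% on NA.

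6 of the 10 loci with the most reads were spliced transcripts. On sequence 9 at 3948580 to 3950486, a minus-strand transcript had 2649 reads and 3 introns that were each seen in at least 10 reads. On sequence 8, the locus at 220020 to 223051 had 2474 reads on a plus-strand transcript. Its 4 introns seen in at least 10 reads included one of 1054 bases, from 220992 to 222045, in 266 reads. On sequence 6, the locus at 3977887 to 3980031 had 2266 reads and 6 such introns, and the locus at 3950106 to 3954224 had 1935 reads and 8 such introns, both on the plus strand. The compact locus on sequence 8 at 1117577 to 1117973 had 2230 reads. It had a single intron of 150 bases, from 1117782 to 1117931 on the minus strand, in 1153 reads, and a cDNA of 233 bases between its commonest ends. Its share of 0.998% fell to 0.511% with duplicates counted once and to 0.0830% with both limits on identity and aligned share, which kept 64 of its reads. On sequence NA, the locus at 4069771 to 4071619 had 1891 reads and 4 such introns on the plus strand, and 38.3% of its reads had another place.

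The locus on sequence 14 at 3203887 to 3204115 differed from these in alignment quality. It held 2445 reads with a median identity of 87.5%, and the median read there was 79 bases long with 33 bases aligned. Only 16.8% (interval 15.3 to 18.4) of its reads reached an identity of 95%, against 96.8% to 99.1% at the other 9 loci. Its reads ran almost all in 1 direction, 2378 plus against 67 minus, and none was spliced. Another place on the genome was found for 57.8% of them. Its share of 1.09% fell to 0.508% among reads with exactly 1 alignment, to 0.262% with duplicates counted once and to 0.194% at identity of at least 95%. None of its reads met both limits on identity and aligned share.

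**Figure D2:**
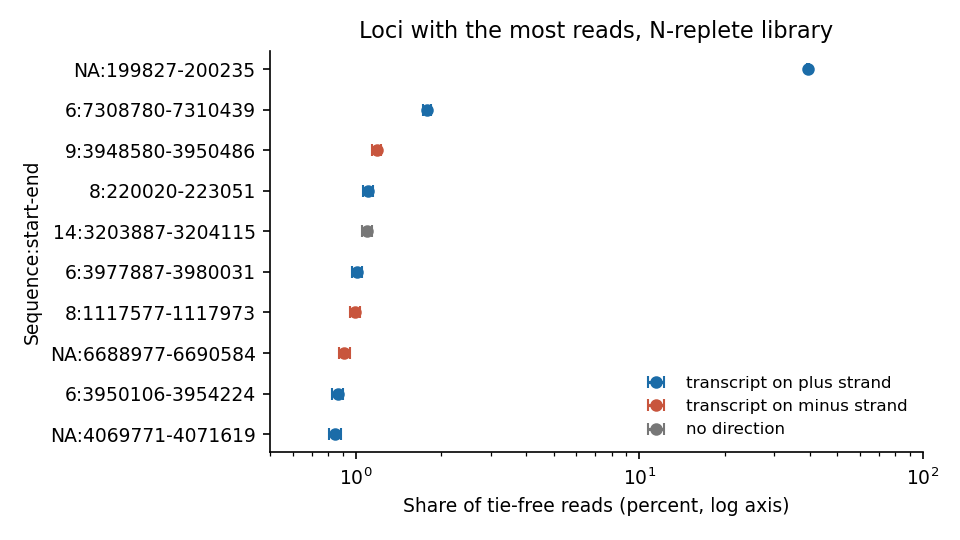
Share of the tie-free reads of the N-replete library, in percent on a log axis, at the 10 loci with the most reads, each named by sequence, start and end. Points are shares, bars are exact 95% binomial intervals and colours give the transcript strand. The locus on NA at 199827 holds 39.4%, and the other loci lie between 0.846% and 1.79%.

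The ends of the cDNAs were visible in the reads as stretches of leading bases that did not align. At loci with a splice direction, most often no leading base was unaligned. This held for 23015 reads along the transcript strand and 22589 along the opposite strand. Among reads with at least 20 leading unaligned bases, the commonest number was 40 along the transcript strand and 50 along the opposite strand. Reads with 34 to 44 leading bases were taken as starting at the 5' end of a cDNA, and those with 45 to 57 as starting at the poly(A) side. The direction matched splicing for 94.0% (interval 93.6 to 94.4) of 12421 reads of the first kind and for 95.5% (interval 95.1 to 95.8) of 12018 reads of the other. Because the ranges were set on these loci, the match describes them and is not an independent test. Among the 345 loci with at least 50 reads, splicing gave a direction to 283 and cDNA ends to 250, and both gave the same direction at all 211 loci where both applied. Of the 33 loci without a directed spliced read, 20 received a direction from the ends. Splicing could not check the direction at these 20, which include the narrow locus on sequence 2 at 8122487 to 8122512. Whether all 20 are transcripts was not tested.

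**Figure D3:**
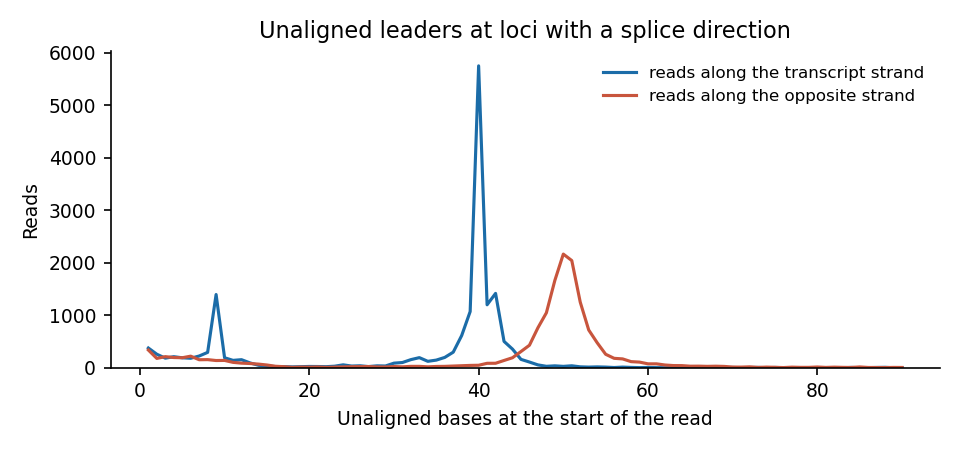
Number of reads (y axis) by the number of unaligned bases at the start of the read (x axis, in bases) at loci with a splice direction in the N-replete library. Reads without a leading unaligned base, the commonest kind, are left out of the plot. Lines separate reads along the transcript strand, with a peak at 40 bases, from reads along the opposite strand, with a peak at 50 bases.

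The 3' ends were more sharply placed than the 5' ends. A median of 92.0% of the 3' end reads of a locus lay within 5 bases of the commonest position (238 loci, quartiles 82.4 and 98.4), against 81.1% of the 5' end reads (218 loci, quartiles 63.6 and 90.8). The 5' end was the tighter one at 58 of the 202 loci with both ends (28.7%, interval 22.6 to 35.5). Between the commonest ends, these 202 loci had a median cDNA length of 1038 bases over a median genome distance of 1993.5 bases, with a median of 4 introns.

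Reads were spread almost evenly along the covered exonic sequence, and a small excess toward the 3' end depended on which reads were used. Parts of a transcript without reads lie outside this measure, so it cannot show evenness over whole transcripts. Over the 283 loci with a splice direction, the 5 bins nearest the 3' end held 52.1% ± 7.56 (SD over 283 loci) of the coverage in 10 equal bins of the covered exonic sequence. The mean had a 95% interval of 51.2 to 53.0. This share exceeded the share of the other bins at 173 of the 283 loci (61.1%, interval 55.2 to 66.8). Among reads with an identity of at least 95% and an aligned share of at least 90%, the mean was 49.7% (interval 48.6 to 50.9, 197 loci), and the excess was no longer seen. By construction, the limit on aligned share removes reads with long unaligned stretches, such as end reads, and fewer loci entered. Whether the excess was lost through that removal was not tested. The mean per bin ran from 8.98% to 11.5%; the SD over loci within a bin ran from 2.55 to 4.77.

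**Figure D4:**
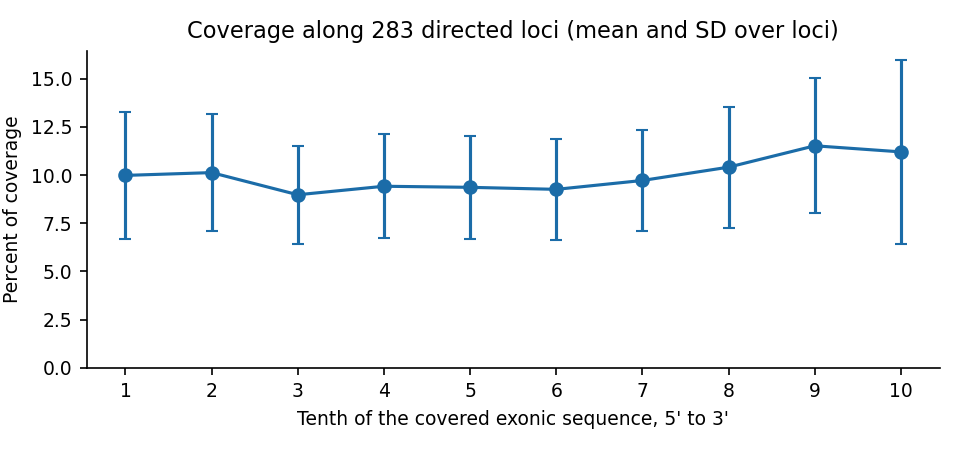
Mean share of read coverage, in percent (y axis), in each of 10 equal bins of the covered exonic sequence from 5' to 3' (x axis), over 283 loci with a splice direction in the N-replete library. Bars are the SD over loci. The means lie between 8.98% and 11.5%.

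Splicing was seen in 45124 tie-free reads, 20.2% (interval 20.03 to 20.4) of all and 33.3% (interval 33.0 to 33.5) of those outside the most abundant locus. These reads defined 9531 distinct introns with a splice direction, of which 4625 were seen in at least 2 reads and 864 in at least 10. The median intron length was 217 bases (95% interval 214 to 220), with quartiles of 150 and 310. It was 213 bases (interval 209 to 217) for introns seen in at least 2 reads and 200 bases (interval 193 to 208) for those seen in at least 10. The alignment call set the limits for introns at 1000 bases, and 77 introns were longer than that. Longer introns can be missed under these limits, so the count does not give the frequency of long introns. The lengths above describe introns placed under them. Of 61358 splice events, 98.0% (interval 97.9 to 98.1) had GT-AG borders, 1.27% (interval 1.18 to 1.36) had GC-AG and 0.0326% had AT-AC. The aligner prefers such borders when it places a gap, so these shares depend partly on it. Internal exons had a median of 77 bases, among exons short enough to lie inside a read. Unlike the introns, these 16231 exons were counted in each read that held them, so abundant transcripts weigh more. An intron length divisible by 3 was found for 32.4% (interval 31.5 to 33.4) of the introns.

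**Figure D5:**
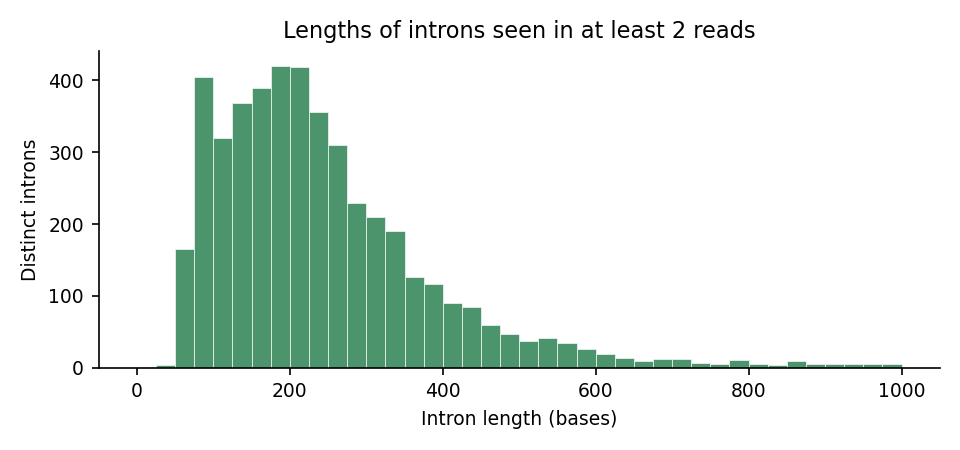
Lengths of the 4625 distinct introns seen in at least 2 reads of the N-replete library, up to 1000 bases. The x axis gives intron length in bases in bins of 25 bases and the y axis the number of introns. The fullest bin holds 420 introns of 175 to 200 bases.

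Read-through was counted at introns seen spliced in at least 2 reads. This choice favours low values, and the classes below are set by the same spliced reads that enter the share. Unspliced reads crossed a boundary of such an intron in 2166 of 114608 crossings (1.89%, interval 1.81 to 1.97). The share was 0.225% for introns with 50 or more spliced reads and 10.7% for introns with 2 to 4. In that last class 96.8% of the introns had no such crossing, and without the 15 introns read through in most of their crossings its share was 0.724%. Over all classes, 16 introns that were read through in most of their crossings accounted for most of the total, and without them it was 0.376%. Few alternative partners were seen at this depth. Of 4610 donor sites in introns with at least 2 reads, 14 joined 2 or more acceptors. Of 4604 acceptor sites, 20 joined 2 or more donors. Among the 864 introns with at least 10 reads, neither occurred. Each partner had to reach the same minimum of reads. With 2 to 4 spliced reads at 2946 of the 4625 introns, rarer partners could go unseen.

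Reads were unevenly spread over the chromosomes. Outside the most abundant locus, sequence 6 held 13.3% (interval 13.1 to 13.5) of the reads, sequence 12 held 13.2% (interval 13.0 to 13.4) and sequence 2 held 11.5% (interval 11.3 to 11.7). The lowest share was 0.922% (interval 0.872 to 0.975), on sequence 15. These shares were not scaled to chromosome length, which was implied as 9355449 bases for sequence 12 and 3066274 bases for sequence 15. The number of loci with at least 10 reads per megabase ran from 4.99 on sequence 4 to 14.96 on sequence 12, with a median of 8.27 over 16 chromosomes of known length. On sequence 14, 10.0% of the reads had a splice direction, the lowest share of the 17 numbered sequences, against 51.6% on sequence 4. Both values moved when single loci were left out. Without the locus with the most reads on each sequence, the shares were 17.4% (interval 16.1 to 18.8) on sequence 14 and 30.8% (interval 28.6 to 33.2) on sequence 4, where the locus left out at 34033 to 35003 had 783 directed spliced reads among 871. The locus at 3203887 and its neighbour at 3204140 to 3204310 held 3066 reads and no spliced read, with median identities of 87.5% and 85.3%. Without both loci, the share on sequence 14 was 21.5% (interval 19.9 to 23.1).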

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

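All tests in this part were chosen, or given their final form, after the results were seen. Only the N-replete library was analysed, so no biological explanation from the design was tested for any pattern. A pair of results concern data that the locus counts do not use, namely tied reads and unaligned read starts, and were singled out for that reason alone. Reads that scored equally at several places numbered 16189, of which 7406 (45.7%, interval 44.98 to 46.5) had their best place on sequence 14. Of the tied reads, 7307 lay between bases 4012672 and 4112392, near the end of that sequence at 4114342, with a median of 6 places found. Reads whose first 20 or more bases did not align numbered 139368, or 58.2% of the aligned reads, and 127979 of these reads were themselves in the locus counts by their aligned bases.

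The 167-base product with 39.4% of the tie-free reads was weighed first. Sharing of reads between repeated places would need most of its reads to have a second place, and 7.27% did with tied reads included. A general preference of the PCR or sequencing for short cDNA would make reads fall with cDNA length at other loci, if cDNAs gave equally many reads each. Reads were spread along the covered exonic sequence, so longer cDNAs can give more reads, which can hide such a fall. Over the 201 other loci with both ends, Spearman's rho across loci was 0.195, but loci with few reads need enough end reads to enter, which favours a positive value. For both reasons, that first value does not argue against the explanation. The test was then limited to the 102 loci with at least 200 reads, nearly all of which have both ends, and rho was 0.103 (permutation p = 0.3, two-sided; Pearson's r of the log2 values 0.0795). With minimums of 100 and 400 reads, rho was 0.160 and -0.0573, so its sign depends on the minimum. For these reasons, and because loci are not independent replicates, the test does not decide on a general preference. Only 1 of the 102 loci had a cDNA of up to 200 bases, so a preference confined to very short products also stays open. Amplification of this product alone and true abundance stay open as well. The product lies within the first 350000 bases of sequence NA, which are weighed next. The sources of sequence left open there, such as an organelle genome or bacterial sequence, therefore stay open for this product too.

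The absence of spliced reads on the first 350000 bases of sequence NA was weighed next. Outside the most abundant locus, 0 of 1219 reads there had a splice direction, against 30.8% of 9844 reads on the rest of NA. Reads too short to cross introns would give few spliced reads at the same aligned lengths elsewhere, but chromosome reads weighted to those lengths had a splice direction in 29.1% of cases. The part was made to end just before the first directed spliced read, at base 352022, so its count of 0 and the upper 95% bound of 0.302% were fixed by that choice and do not test a sequence without spliceosomal introns, such as an organelle genome. That explanation stays open, as does bacterial or other intronless sequence. Reads there had a median identity of 96.2%, against 98.9% on the rest of NA, and 0 of the 779 at identity of at least 95% had a splice direction, a count that the same choice fixed. With no such boundary, the longest run of neighbouring loci with at least 10 reads and no directed spliced read, leaving out the most abundant locus, was 22 loci on NA (6821 to 290971), and the next longest on any sequence was 5.

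The locus on sequence 14 at 3203887 to 3204115, among the 10 with the most reads, had a low identity. Chance or adaptor alignments would leave few reads at an identity of 95%, and a transcript would leave most. The observed 16.8% (interval 15.3 to 18.4) lies between both, so the explanations cannot be told apart by it. None of its 2445 reads met identity of at least 95% and an aligned share of at least 90%, but 33 aligned bases in a 79-base read cannot meet the second limit whatever their source.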

How the results depend on the processing

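Identity of at least 95% alone, aligned-base loci, a minimum of reads per intron, leaving out the most abundant locus or the largest loci of a sequence, and leaving out introns read through in most crossings were chosen after seeing the data. The number of loci with at least 10 reads stayed between 764 and 1061 (1034 as reported). The median intron length was 217 to 218 bases under other read or gap settings, but 213 for introns seen in at least 2 reads and 200 for at least 10. The mean coverage share nearest the 3' end (52.1%, interval 51.2 to 53.0) was 51.8% at identity of at least 95%. It was 49.7% when the aligned share was also required, outside that interval and on the other side of an even spread. That limit removes reads with long unaligned stretches, such as end reads, by construction. The 239585 aligned reads became 203010 with 1 alignment only, 223169 at identity of at least 95%, and 80749 when an aligned share of 90% was also required. The share of the most abundant locus (39.4%) was 41.8% among reads with 1 alignment, 37.5% with ties split and 40.6% at identity of at least 95%. It was 0.572% with the aligned share also required, which by construction removes reads with long unaligned stretches, and 1.41% with duplicates counted once, which by construction caps a product with fixed ends. The share of the next 9 loci (16.2%) was 11.5%, 15.5%, 15.4%, 14.9% and 12.4% in the same order of settings. The share of spliced reads (20.2%) was 40.6% with identity and aligned share required, 20.9% with identity alone and 33.3% without the most abundant locus. The share of boundaries read through (1.89%) was 0.461% with both limits, 1.499% with identity alone, 1.62% with gaps of at least 50 bases and 0.376% without the 16 introns read through in most crossings. Apart from the constructions named, the cause was not tested. Of 60 shares of single loci, 43 moved beyond their interval, 24 up and 19 down. Falls by over 1.5 times are given beside the loci. Rises by over 1.5 times reached 1.47% to 3.96% at 6 loci with both limits and 1.39% to 2.78% at 4 loci with duplicates counted once. A smaller share of the most abundant locus raises the others through the total, and leaving it out raised the other 9 shares by construction. Of the 10 named loci, 7 stayed among the 10 with the most reads with 1 alignment only, and 7 with both limits, where the most abundant locus itself (now rank 32), the locus on 14 and the one on 8 at 1117577 dropped out, 8 with duplicates counted once and 9 with ties split. With 25% of the reads drawn at random, 435 loci had at least 10 reads, with 50% 631 and with 75% 842, so the number of loci is limited by depth. No paired analysis was possible because only 1 library was analysed. Not run were counting by exons or by gene strand, the alternatives of the gene lists, those of the comparison of conditions, and the 3' coverage share under gaps of at least 50 bases.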

Other observations

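The locus on sequence 17 at 935071 to 937358, chosen after its values were seen, was the 1 locus of those with at least 20 directed spliced reads whose reads ran in both splice directions, with at least 20% in each. It held 1159 reads with a median identity of 95%. Of its spliced reads, 108 ran along the plus strand, with introns of 216 bases (935458 to 935673, 49 reads) and 250 bases (935892 to 936141, 58 reads). Another 96 reads carried a gap of 30 bases in the minus direction, from 937012 to 937041. By its cDNA ends the transcript ran along the plus strand.

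Among the tied reads of the most abundant locus, 3640 of 3653 were also listed on sequence NA between bases 221105 and 221584, with a median of 45 aligned bases. With ties split equally, that second place held 1947.83 reads and entered the 10 loci with the most reads. Neighbouring directed loci within 50000 bases of each other were transcribed from the same strand in 29 of 58 pairs (50.0%, interval 36.6 to 63.4).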
